A study of Mus musculus with 13 samples.

How the data were processed

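The samples are 13 poly(A) RNA libraries from mouse melanoma cell lines grown in culture, with doxycycline in the medium for 0, 6 or 48 h. Doxycycline is an antibiotic used to switch on genes placed under an inducible promoter. The series concerns soluble adenylyl cyclase (sAC), an enzyme that makes cyclic AMP (cAMP) and is encoded in the mouse by Adcy10, expressed in chosen compartments of the cell. The groups were taken from the sample titles. They are NLS t0, NLS t6 and NLS t48 with 3 libraries each (cell line numbers 6, 7 and 16) and LacZ t0 and LacZ t48 with 2 libraries each (cell line numbers 10 and 12). The compartment label of the NLS lines under doxycycline is nuclear. The LacZ t48 libraries carry the same compartment label, against their titles, and were kept with the LacZ lines. Cytoplasmic and mitochondrial expression, which the series names, was not analysed here. The labels do not say whether libraries of a group came from separate cultures beyond their cell line numbers, so p-values measure the spread between these libraries.

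RNA was extracted with Trizol and made into stranded paired-end libraries with a Truseq mRNA kit, per the labels' protocols. The authors quantified transcripts with Salmon 1.2.0 on GRCm38, per the submitters' processing notes. Salmon shares reads among transcripts that fit them and gives estimated counts. The deposited tables hold estimated counts per transcript, TPM values (a length-scaled unit) and effective lengths; the transcript set and the options are not given in the sources used here. Because reads that fit several transcripts are divided by the model, values of genes with near-identical copies, such as Gbp2b, Gbp9, Akr1c13, the Oas and Ifit families and the H2 genes, are uncertain.

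Of 116546 transcripts, 115977 (99.5%) were matched by identifier to a GRCm38 gene annotation, and their estimated counts were summed over 35498 genes and rounded to whole numbers. Unmatched transcripts held 0.121 to 0.165% of the reads of a library and were left out. Library totals were 18512887 to 22584628 estimated reads. No pair of libraries of 1 group agreed within sampling noise. The lowest chi-square per degree of freedom between 2 libraries of a group was 7.26.

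Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the edgeR filter on low counts (13044 genes kept), robust estimates of spread and 1 fit over all 13 libraries with 5 group means. P-values were adjusted by Benjamini-Hochberg and called below 0.05. Levels are CPM, the usual depth-scaled counts, on TMM library sizes. Standard errors of log2 fold changes were derived from the test statistic. Fold changes against groups with 0 reads are given as bounds against a floor of 3 counts per library, which covers counting error only. Intervals of Adcy10 are exact 95% Poisson intervals for counting error.

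The comparisons fixed before the data were examined were NLS t6 against t0, NLS t48 against t0, LacZ t48 against t0, the difference of the last 2 responses (an interaction), NLS t48 against t6, and NLS t0 against LacZ t0. Comparisons between cell line numbers, with the time label as a block, were added after the data were seen. The 26 gene lists, fixed beforehand with 492 entries, covered cAMP and CREB targets, the cAMP machinery, YAP/TAZ targets and the Hippo pathway, pigment and melanoma states, the cell cycle, p53, stress, mitochondria, metabolism, interferon, antigen presentation, ERK, Wnt and TGF-beta output, matrix, and markers of fibroblasts, leukocytes, keratinocytes and endothelium. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the 25 lists with at least 2 tested members; fry and camera with an estimated correlation were run beside it. The endothelial list had 1 tested member and was not tested.

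Genes were named by a fixed rule. For NLS t6 and NLS t48 against t0 and for the interaction these were the 8 largest increases and the 8 largest decreases by log2 fold change past the threshold, with mean log2 CPM of at least 1, a symbol that is not a predicted-gene or clone name or a pseudogene, and the same direction in every cell line (for the interaction, the same direction of the NLS change, and for NLS t0 against LacZ t0, no overlap of the groups). The other comparisons took 5 and 5, and the added ones 8 and 8. From each list came up to 3 members higher and 3 lower with the smallest p, or the member with the smallest p where none passed. Adcy10, Nr4a1, Crem, Ccn1, Ccn2, Yap1, Mitf and Cdkn1a were always included. Some genes that the rule names are not reported here.

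The cell line numbers pair the libraries, since the same number marks the same cell line in the labels. Deviations from the group means correlated between NLS libraries with the same number at r = 0.00943 to 0.249 over 9 pairs and between those with different numbers at r = -0.226 to 0.0493 over 18 pairs, across genes. The 2 LacZ pairs gave r = -0.0265. With 2 libraries per group the deviations mirror each other, so both pairs hold the same value. No method of the study was given, and the fit without the block was taken as the main one. The main fit leaves out this pairing, so a change alike in every line can miss the threshold where lines differ in level. The blocked value is printed beside a result where it changes a call or moves a count by over 1.5 times.

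The fit was tested on simulated counts made from the real means, with 200 changed genes among about 12812 tested. For NLS t48 against t0 it recovered 60.61% of genes changed by 1.5-fold, 83.58% at 2-fold and 92.31% at 4-fold, with 7 unchanged genes called. For NLS t6 against t0 the shares were 76.92%, 71.64% and 84.85%, with 9 unchanged genes called. For LacZ t48 against t0 they were 50%, 70.31% and 92.19%, with 7 unchanged genes called. Alternatives covered a block by cell line, other size factors, DESeq2 1.42.0, no filter on low counts, only the libraries compared, counts rebuilt from TPM and transcript length, a minimum of 2-fold, and leaving out each library and each cell line.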

Results

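Gene expression was measured by mRNA sequencing in 13 libraries of mouse melanoma cell lines. The lines titled NLS were sampled before doxycycline (t0) and after 6 h (t6) and 48 h (t48), with 3 libraries at each time. The lines titled LacZ, the control lines, were sampled at t0 and t48 with 2 libraries each. Depth was similar, with 18512887 to 22584628 estimated reads per library. Transcripts of the pigment lineage were scarce in all 13 libraries. Mitf, the master regulator of melanocytes, lay between 2.76 and 5.37 CPM, Tyr, which encodes tyrosinase, between 0.167 and 0.933 CPM, and Sox10, a neural crest factor, at up to 0.0512 CPM. Collagen transcripts were abundant, with Col1a1 between 2560 and 6920 CPM. Of leukocyte genes, Ptprc reached at most 0.0512 CPM and Lyz2 0.69 CPM, while Cd68 lay between 5.64 and 14.1 CPM.

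Adcy10, the gene of soluble adenylyl cyclase (ENSMUSG00000026567, GRCm38 chromosome 1, 165485183 to 165576774, plus strand), was examined first because its induction by doxycycline is what the time labels stand for. Its reads did not follow the time labels. In cell line 6 the level was 365.6 CPM in the library labelled t0 (95% interval 358 to 374), 371.2 CPM (363 to 379) at t6 and 339.2 CPM (331 to 347) at t48. Cell line 7 gave 200.4 CPM (195 to 206), 181.2 CPM (175 to 187) and 199.1 CPM (193 to 205) at the same labels. Cell line 16 had 0.671 CPM (0.367 to 1.13), 1.19 CPM (0.78 to 1.75) and 1.22 CPM (0.774 to 1.83). The LacZ libraries had 0 to 3 Adcy10 reads each, at most 0.167 CPM. Relative to the labelled t0, the ratio at t6 was 1.02 in line 6, 0.904 in line 7 and 1.78 in line 16, and at t48 0.928, 0.994 and 1.82. The edgeR log2 fold changes were -0.04 (SE 1.81, adjusted p = 0.994) at t6 and -0.07 (SE 1.81, adjusted p = 0.984) at t48. Adcy10 mRNA thus did not rise with the time labels in lines 6 and 7. Expression that does not depend on doxycycline would give such values under correct labels, and was not tested. A construct of another species, or one lacking parts, may reach the mouse transcripts only in part. Every direction below is a difference between the libraries labelled with those times.

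**Figure D1:**
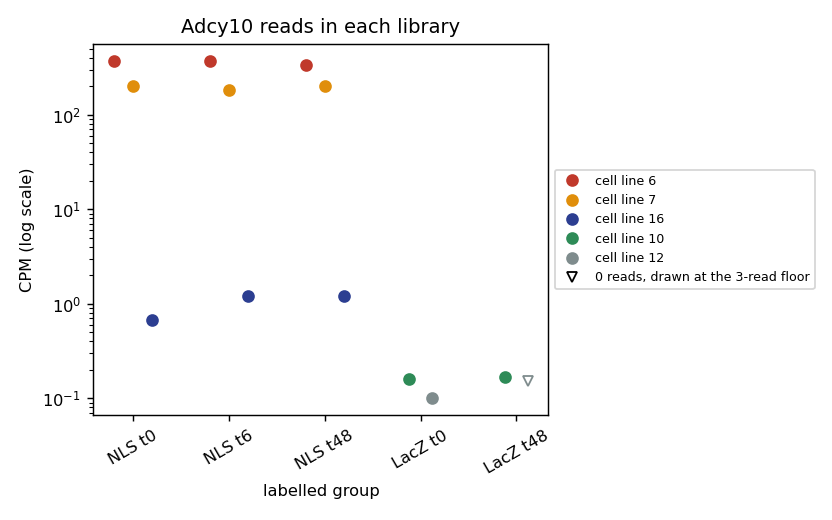
Adcy10 level per library in CPM on a log axis, by labelled group, with 1 point per library coloured by cell line number and the library without reads drawn as an open triangle at the floor of 3 reads. Lines 6 and 7 lie between 181.2 and 371.2 CPM under all 3 time labels and line 16 at up to 1.22 CPM.

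The libraries labelled NLS t6 were compared with those labelled NLS t0 to show the early response to doxycycline. Several genes were near 0 at the labelled t0 and present at t6 in all 3 lines. Tshz3, which encodes a zinc finger transcription factor, had no reads at t0 and 6.87 ± 0.42 CPM at t6 (SD, n = 3), at least 50.5-fold higher. Cadm1, a cell adhesion gene, was at 8.86 ± 1.27 against 0.0295 ± 0.0511 CPM, Adam23 at 6.66 ± 0.64 against 0.0588 ± 0.0677 CPM, Igf2bp3, an RNA-binding protein gene, at 13.5 ± 1.04 against 0.17 ± 0.14 CPM, and Zfp532 at 6.29 ± 1.12 against 0.077 ± 0.072 CPM. Prelid2, Mocos and Zdhhc15 had the remaining large increases. Lower at t6 were Fndc1 (log2 fold change -4.23, SE 0.17, adjusted p = 1.01e-08), Ccn5 (-3.37, SE 0.35), Ndufa4l2 (-3.26, SE 0.15), Cntn2 (-2.86, SE 0.60), Abi3bp (-2.49, SE 0.65), Ankrd1 (-2.37, SE 0.41), Selenbp1 (-2.34, SE 0.37) and Rcan2 (-2.14, SE 0.24). The call of Abi3bp was lost in 4 of 9 fits that left out a library or a line (adjusted p up to 0.129, without line 16). Ankrd1 and Cntn2 lost theirs without line 16 alone (adjusted p = 0.0726 and 0.0842).

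Genes that respond to ERK signalling were higher at the labelled t6, with 9 of 18 tested members higher and none lower (11 higher when adjusted over the list alone). Etv4 was at 34 ± 2.88 against 14.9 ± 1.54 CPM and Dusp6, a phosphatase that dampens ERK, at 19.9 ± 1.03 against 11.4 ± 1.42 CPM. Camera gave this list an adjusted p = 2.72e-05, and an adjusted p = 0.148 with an estimated correlation. Of 22 glycolysis and hypoxia genes 11 were lower and none higher, over all genes and when adjusted over the list alone, among them Pdk1 (log2 fold change -0.70), Tpi1 (-0.45) and Pgam1 (-0.43). Its adjusted p was 3.71e-05, and the adjusted p = 0.293 with an estimated correlation. Extracellular matrix genes went both ways, 5 higher and 11 lower of 23 (6 and 12 adjusted over the list alone): Col3a1 (-0.76), Lama4 (-0.93) and Sparc (-0.40) were lower while Col4a2 (0.85) and Thbs1 (1.07) were higher, as was Col4a1 (149.1 ± 17.1 against 74.5 ± 4.61 CPM). The list's adjusted p was 0.00252, and the adjusted p = 0.583 with an estimated correlation. Sterol synthesis genes had 2 higher and 9 lower of 20 (2 and 10 adjusted over the list alone; camera adjusted p = 0.0122, and adjusted p = 0.535 with an estimated correlation), with Sqle, Msmo1 and Mvk lower and Dhcr7 higher. Without line 6 Thbs1 and Mvk lost their calls (adjusted p = 0.0644 and 0.0639). Fibroblast markers had 3 lower of 7 tested, also adjusted over the list alone (adjusted p = 0.00252, and adjusted p = 0.148 with an estimated correlation). Pigment genes had 2 higher of 8, also adjusted over the list alone (adjusted p = 0.0169, and 0.148 as the adjusted p with an estimated correlation), and the integrated stress response list 5 lower of 20, 7 adjusted over the list alone (adjusted p = 0.0253, and 0.589 as the adjusted p with an estimated correlation). This last list lost its call without line 6 (adjusted p = 0.125) and without line 16 (0.0588).

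cAMP and CREB targets, the genes most directly tied to sAC, had 2 members higher and 1 lower of 22 at the labelled t6 (1 higher and 0 lower adjusted over the list alone). Egr1 and Id1 were higher (log2 fold changes 0.51 and 0.41) and Dusp1 lower (-0.51). The list did not pass (adjusted p = 0.177; 0.0316 without line 6). Crem (0.52, adjusted p = 0.0628) and Nr4a1 (0.31, adjusted p = 0.747), both CREB targets, did not pass. Of 22 YAP/TAZ targets 3 were higher and 3 lower (5 and 3 adjusted over the list alone; list adjusted p = 0.87). Arhgef17 (1.21), Foxf2 (0.87) and Axl (0.36) were higher, and Ankrd1, Nt5e (-0.88) and Amotl2 (-0.27) lower. Of 9 fits that left out a library or a line, Id1 and Dusp1 lost their calls in 6 each (adjusted p up to 0.291 and 0.232, without line 16) and Amotl2 in 5 (up to 0.184, without line 6). Nt5e and Ankrd1 lost theirs without line 16 (adjusted p = 0.0521 and 0.0726) and Foxf2 without line 6 (0.0594). Ccn1 (0.02), Yap1 (-0.07), Cdkn1a (0.10) and Mitf (0.36) did not pass, with adjusted p = 0.947, 0.381, 0.85 and 0.11. Ccn2 (-0.30, adjusted p = 0.666) passed with the cell line as a block (adjusted p = 0.0236). With the block 5 more lists passed: the Hippo pathway, dedifferentiation and G2/M genes higher, and chaperones and the respiratory chain lower. Their adjusted p was 0.0478, 0.00553, 0.0272, 0.0272 and 0.0291, and adjusted p = 0.476, 0.379, 0.577, 0.379 and 0.594 with an estimated correlation and the block. In all, edgeR called 2716 of 13044 genes, 1512 higher and 1204 lower, of which 424 differed by at least 2-fold. The blocked fit called 4527. Without cell line 6 the count was 988, without cell line 16, which has few Adcy10 reads, 1354, and with only the 6 compared libraries 1805.

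**Figure D2:**
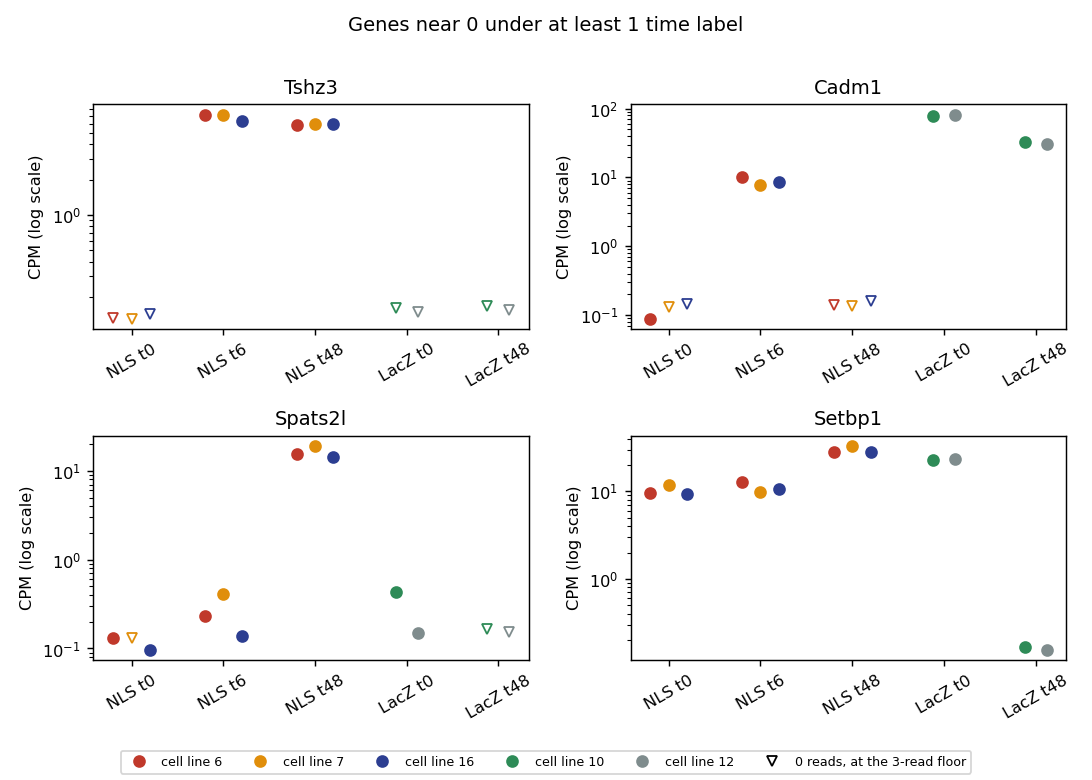
Level in CPM on a log axis of Tshz3, Cadm1, Spats2l and Setbp1 in each of the 13 libraries, by labelled group, with points coloured by cell line number and libraries without reads drawn as open triangles at the floor of 3 reads. Within the NLS or within the LacZ libraries, each gene is near 0 in every library of at least 1 time label and at several CPM or more in every library of another. An example is Setbp1 at 23.2 ± 0.23 CPM in LacZ t0 and 0.16 ± 0.01 CPM in LacZ t48. Setbp1 is at 9.39 CPM or more in every NLS library, and Cadm1 at 30.7 CPM or more in every LacZ library.

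The libraries labelled NLS t48 were compared with NLS t0 for the late response. Matrix genes were higher and sterol synthesis genes lower. Of 23 matrix genes 17 were higher and 1 lower, also when adjusted over the list alone. Thbs2, a matrix glycoprotein gene, was at 1015 ± 51.6 against 396.9 ± 7.77 CPM (SD, n = 3), Col4a1 at 193.4 ± 10.9 against 74.5 ± 4.61 CPM and Col3a1 at 5353 ± 244 against 2853 ± 134 CPM, while Bgn was lower (log2 fold change -0.26), a call lost in 2 of 9 fits that left out a library or a line (adjusted p up to 0.0832, without line 16). The list's adjusted p was 4.87e-14, and the adjusted p = 0.109 with an estimated correlation. Fibroblast markers, which share Col3a1 and other collagens with that list, had 4 higher of 7, also adjusted over the list alone (adjusted p = 0.0168, and adjusted p = 0.109 with an estimated correlation). Of 20 sterol synthesis genes 18 were lower and 1 higher, also adjusted over the list alone. Msmo1 (-0.78, SE 0.06) and Fdps (-0.53, SE 0.05), enzymes of the cholesterol pathway, were lower and Dhcr7 (0.43, SE 0.06) higher. Its adjusted p was 5.47e-12, and the adjusted p = 0.0759 with an estimated correlation. Interferon-stimulated genes had 6 lower and none higher of 26, over all genes and when adjusted over the list alone, with Oas3 (-2.15), Oasl1 (-1.97) and Bst2 (-0.51) in front. Camera gave an adjusted p = 0.0225, and an adjusted p = 0.818 with an estimated correlation.

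The largest increases at the labelled t48 were again between presence and near absence. Tshz3 had 5.9 ± 0.06 CPM and no reads at t0, at least 43.4-fold higher. Adam23 was at 23.3 ± 2.74 against 0.0588 ± 0.0677 CPM, Slc8a1, a sodium-calcium exchanger gene, at 14.6 ± 1.81 against 0.104 ± 0.065 CPM, Spats2l at 16.2 ± 2.48 against 0.076 ± 0.069 CPM, and Armcx2 at 12.8 ± 0.49 against 0.12 ± 0.09 CPM. Prelid2, Cachd1 and Zfp532 completed the 8 largest increases. Lower were Unc5c, a netrin receptor gene (log2 fold change -3.76, SE 0.23, adjusted p = 8.71e-08), Slurp1 (-2.62, SE 0.27), Dynap (-2.50, SE 0.32), Hgf (-2.46, SE 0.43), Gbp9 (-2.38, SE 0.50), Blnk (-2.36, SE 0.14), Dock8 (-2.27, SE 0.10) and Msln (-2.25, SE 0.25).

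cAMP and CREB targets had 4 higher and none lower of 22 at the labelled t48, also adjusted over the list alone. Btg2 (log2 fold change 1.02), Per2 (0.96) and Bdnf (0.51) were among them, and the list did not pass (adjusted p = 0.216). Crem (0.19, adjusted p = 0.492) and Nr4a1 (0.16, adjusted p = 0.866) did not pass. Of 22 YAP/TAZ targets 9 were higher and 3 lower (10 and 4 adjusted over the list alone), with Arhgef17 (1.34), F3 (1.19) and Ptpn14 (0.32) higher and Myof (-0.35), Dock5 (-0.29) and Axl (-0.17) lower. The call of Axl was lost in 6 of 9 fits that left out a library or a line (adjusted p up to 0.126, without line 6). The list did not pass without the block (adjusted p = 0.15; 0.00306 without line 16) and passed with it (adjusted p = 0.000318, and adjusted p = 0.435 with an estimated correlation and the block). Ccn2 (1.11, adjusted p = 0.0801) and Ccn1 (0.19, adjusted p = 0.509) passed with the block only (adjusted p = 1.9e-05 and 0.0124), apart from Ccn2 without line 16 (0.0418). Ccn2 was higher at t48 than at t0 in each NLS line. The levels were 385.1 against 184.9 CPM in line 6, 298.6 against 117.9 CPM in 7 and 541.2 against 266.9 CPM in 16. Yap1 (-0.10), Mitf (-0.28) and Cdkn1a (0.11) did not pass (adjusted p = 0.133, 0.211 and 0.822). The G1/S list (lower, adjusted p = 0.0286) and the TGF-beta list (higher, adjusted p = 0.00921) also passed with the block, with adjusted p = 0.752 and 0.435 with an estimated correlation and the block. EdgeR called 3402 genes, 1932 higher and 1470 lower, 664 of them by at least 2-fold, and 5188 with the block. Without cell line 6 the count was 1596 and without cell line 16 it was 2128.

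**Figure D3:**
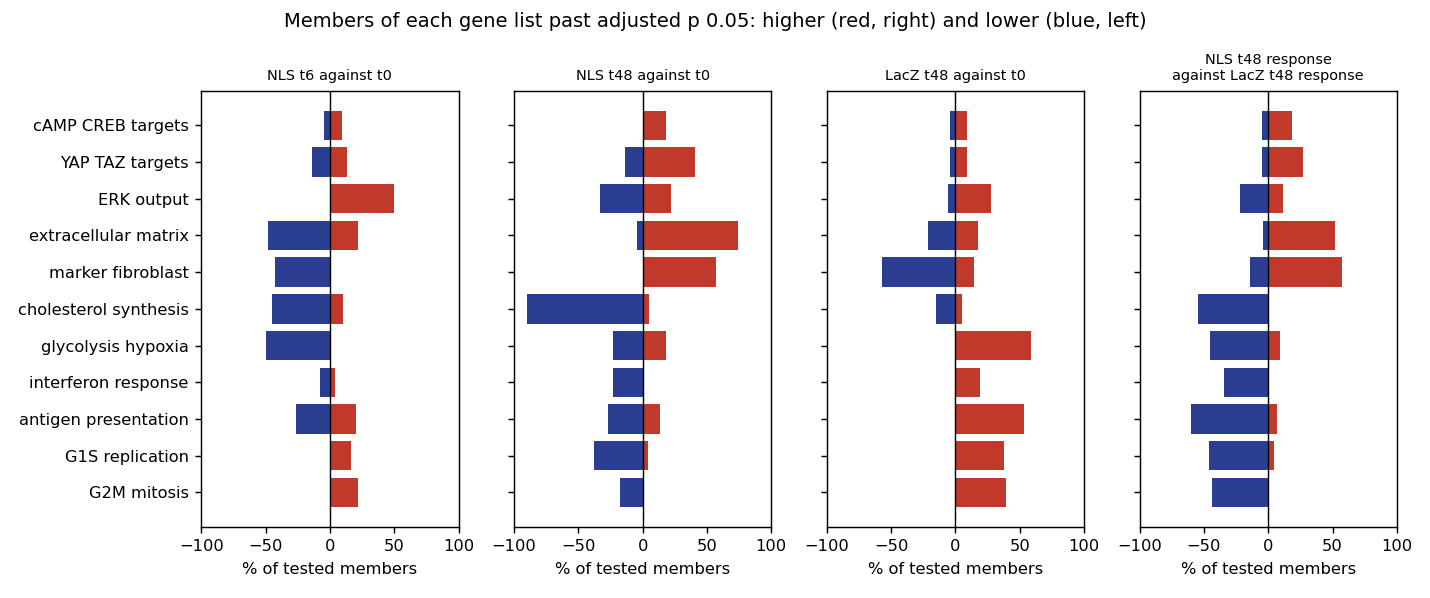
Share of tested members of 11 gene lists that were higher (red, to the right) or lower (blue, to the left) at adjusted p below 0.05, in percent, for the 3 time comparisons and for the NLS response minus the LacZ response. Matrix genes are mostly higher at labelled NLS t48 (17 of 23), sterol synthesis genes mostly lower (18 of 20), and glycolysis genes higher in the LacZ lines (13 of 22).

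The LacZ lines at labelled t48 and t0 show what doxycycline and time do without the NLS construct, by the titles. Antigen presentation genes were higher, 8 of 15 with none lower (9 adjusted over the list alone). Psmb8, an immunoproteasome subunit gene, was at 58.5 ± 2.8 against 8.3 ± 0.01 CPM (SD, n = 2), Tap2, a peptide transporter gene, at 37.4 ± 2.33 against 12.9 ± 0.24 CPM and Psme2 at 180.1 ± 2.82 against 99.5 ± 3.74 CPM. Camera gave the list an adjusted p = 6.12e-15, and an adjusted p = 0.00671 with an estimated correlation. Of 22 glycolysis and hypoxia genes 13 were higher and none lower (16 and 1 adjusted over the list alone), with Egln3, an oxygen-sensing hydroxylase gene (log2 fold change 2.73, SE 0.14), Car9 (1.22, SE 0.17) and Gpi1 (0.56, SE 0.08) (adjusted p = 4.75e-10, and adjusted p = 0.139 with an estimated correlation). G2/M genes had 9 higher and none lower of 23 (11 adjusted over the list alone), among them Kif20a (0.47), Aurka (0.35) and Aurkb (0.48) (adjusted p = 4.37e-05, and adjusted p = 0.608 with an estimated correlation). G1/S genes had 9 higher of 24 (10 adjusted over the list alone; adjusted p = 0.00326, and adjusted p = 0.754 with an estimated correlation). Interferon-stimulated genes had 5 higher of 26 (6 adjusted over the list alone), with Bst2 (0.84), Xaf1 (0.89) and Gbp2 (0.83) (adjusted p = 0.000117, and adjusted p = 0.608 with an estimated correlation). This list did not pass without line 12 (adjusted p = 0.12), nor did Gbp2 (0.0858). In 6 fits that left out a library or a line, Kif20a and Aurkb lost their calls in 2 (adjusted p up to 0.0659 and 0.0658, without line 12) and Aurka in 1 (0.075, without line 10).

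Among single genes, Setbp1 was at 0.16 ± 0.01 against 23.2 ± 0.23 CPM and Foxd1, a forkhead factor gene, at 0.0278 ± 0.0393 against 3.85 ± 0.85 CPM. Robo1 had no reads at the labelled t48 and 1.98 ± 0.38 CPM at t0, at least 12.4-fold lower, and Dact2 was at least 6.76-fold lower. Gbp2b had no reads at t48 and 0.361 ± 0.055 CPM at t0, at least 2.25-fold lower. Ptx3 was at least 7.13-fold higher at t48, with no reads at t0, and Cacna1c had 6 reads at t48 and none at t0. Dclk2 (3.4 ± 0.25 against 0.205 ± 0.063 CPM), Zfp941 (log2 fold change 3.69, SE 0.41) and Akr1c13 (3.51, SE 0.28) were higher. cAMP and CREB targets had 2 higher (Bdnf 0.45, Dusp1 0.77) and 1 lower (Id1 -0.69) of 22, also adjusted over the list alone (list adjusted p = 0.979), and YAP/TAZ targets 2 higher (Axl 0.30, F3 0.74) and 1 lower (Rbms3 -0.62), also adjusted over the list alone (adjusted p = 0.487). In 6 fits that left out a library or a line, Dusp1 and F3 lost their calls each time (adjusted p up to 0.257 and 0.321, without line 12), Bdnf and Id1 in 5 (up to 0.291 without line 10 and 0.186 without line 12), Rbms3 in 4 (up to 0.145, without line 12) and Axl in 2 (up to 0.162, without line 10). Cacna1c lost its call in 5 (up to 0.316, without line 12) and Gbp2b in 1 (0.0708, without line 12). Crem (-0.47, adjusted p = 0.182), Nr4a1 (-0.34, adjusted p = 0.777) and Mitf (0.00, adjusted p = 0.997) did not pass. Pde4b and Nr4a2, also of the cAMP and CREB list, were not called, though each moved alike in both LacZ lines. Pde4b was at 9.949 against 1.287 CPM in line 10 and 12.18 against 1.898 CPM in line 12. Nr4a2 was at 4.224 against 10.88 CPM and 4.452 against 10.79 CPM. The main fit takes a gene's spread from all groups, NLS lines that differ in both genes included. Ccn1 (-0.57, adjusted p = 0.124), Ccn2 (-0.74, adjusted p = 0.353), Cdkn1a (-0.42, adjusted p = 0.45) and Yap1 (0.16, adjusted p = 0.0702) passed only with the block (adjusted p = 4.1e-05, 0.00113, 0.0412 and 0.0239). EdgeR called 2419 genes, 1132 higher and 1287 lower, and 4308 with the block. The count was 533 without cell line 10 and 625 without cell line 12, where 1 library per group is assumed to vary like the others.

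The t48 responses of NLS and LacZ lines were compared directly with an interaction term. They differed in 3045 genes, 1581 more positive and 1464 more negative in the NLS lines, and in 4875 with the block. Of 912 genes called in both lines, 426 had the same direction and 486 opposite directions. Chance overlap of independent lists was 168 genes higher in both, 145 lower in both and 318 opposite, against 223, 203 and 486 observed. Matrix genes had 12 of 23 with a more positive NLS response and 1 more negative (also adjusted over the list alone): Thbs2 (difference of log2 fold changes 1.35, SE 0.09), Col3a1 (1.14, SE 0.08), Postn (4.13, SE 0.42) and, more negative, Lama4 (-0.66, SE 0.12). Its adjusted p was 5.1e-06, and the adjusted p = 0.414 with an estimated correlation. Antigen presentation genes had 9 of 15 more negative and 1 more positive (11 and 2 adjusted over the list alone), with Psmb8 (-2.75), Psme2 (-1.06), Tap2 (-1.53) and, more positive, Nlrc5 (2.13), at adjusted p = 3.37e-08, and adjusted p = 0.0415 with an estimated correlation. Interferon-stimulated genes had 9 of 26 more negative (15 adjusted over the list alone), sterol synthesis genes 11 of 20 (12 adjusted over the list alone, where 1 was more positive), G2/M genes 10 of 23 (also over the list alone). Among them were Bst2 (-1.35), Gbp2 (-1.13), Oas3 (-2.50), Msmo1 (-0.50), Sqle (-0.44), Aurkb (-0.76), Birc5 (-0.62) and Cdc20 (-0.56). Those 3 lists had adjusted p = 5.1e-06, 1.07e-05 and 0.000129, and with an estimated correlation adjusted p = 0.496, 0.218 and 0.496. G1/S genes (11 more negative and 1 more positive of 24; 14 and 1 adjusted over the list alone) and glycolysis genes (10 and 2 of 22; 11 and 2 adjusted over the list alone) passed as well, at adjusted p = 0.000343 and 4.57e-05, and adjusted p = 0.496 and 0.354 with an estimated correlation. Fibroblast markers had 4 more positive and 1 more negative of 7, also adjusted over the list alone (adjusted p = 0.000857, and adjusted p = 0.0706 with an estimated correlation).

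YAP/TAZ targets had 6 more positive and 1 more negative of 22, also adjusted over the list alone, at adjusted p = 0.0495, and adjusted p = 0.496 with an estimated correlation. Without line 12 the list did not pass (adjusted p = 0.179). Arhgef17 (adjusted p = 4.91e-05), Amotl2 (0.52) and Rbms3 (0.82) were more positive and Axl (-0.47) more negative. Ccn1 (0.77, adjusted p = 0.0986), Ccn2 (1.84, adjusted p = 0.0719) and Cdkn1a (0.52, adjusted p = 0.441) passed with the block only (adjusted p = 1.81e-05, 1.84e-05 and 0.0307), apart from Ccn1 and Ccn2 without line 16 (0.00243 and 0.0241). Yap1 itself was more negative (-0.27, adjusted p = 0.0221), a call lost in 8 of 15 fits that left out a library or a line (adjusted p up to 0.122, without line 12). Amotl2 and Rbms3 lost theirs in 2 (up to 0.116 without line 10 and 0.0666 without line 12). cAMP and CREB targets had 4 more positive and 1 more negative of 22, also adjusted over the list alone: Per2 (1.15), Btg2 (0.96), Id1 (0.82) and Rgs2 (-2.48), and the list did not pass (adjusted p = 0.349). Rgs2 lost its call in 10 of the 15 fits (adjusted p up to 0.199, without line 10), and Btg2 and Id1 theirs in 3 (up to 0.111 and 0.121, without line 12). Crem (0.66, adjusted p = 0.127), Nr4a1 (0.50, adjusted p = 0.732) and Mitf (-0.28, adjusted p = 0.454) did not pass. Among the largest differences, Spats2l and Vat1l were at 16.2 ± 2.48 and 19.8 ± 3.31 CPM in NLS t48 and averaged at most 0.531 CPM in each of the other 4 groups. Adam23 was at 23.3 ± 2.74 CPM in NLS t48, 6.66 ± 0.64 CPM in NLS t6 and at most 0.0588 CPM on average in NLS t0 and the LacZ groups. Tspan7, a tetraspanin gene, was lower in NLS t48 than t0 (5.04 ± 0.27 against 19.8 ± 0.7 CPM) and higher in LacZ t48 than t0 (53.7 ± 0.31 against 11.4 ± 0.68 CPM). Setbp1 was higher in NLS t48 than t0 (29.6 ± 2.75 against 10.3 ± 1.37 CPM) and lower in LacZ t48 than t0 (0.16 ± 0.01 against 23.2 ± 0.23 CPM). Robo1, Dact2, Spry1 and Zdhhc15 were more positive, and Unc5c, Slurp1, Prkg1, Abi3bp, Akr1c13, Cacna1c and Ptx3 more negative. Several of these calls were lost in some of the 15 fits: Cacna1c in 11, Abi3bp in 9 and Ptx3 in 6 (adjusted p up to 0.329, 0.166 and 0.169, without line 12). Vat1l lost its call in 6 and Adam23 in 2, among them the fit without the LacZ t0 library of line 10. Adam23 had 1 read in that library and none in the other LacZ libraries. That fit therefore cannot estimate the LacZ change of Adam23. The count fell to 1296 without cell line 10, 1594 without 12 and 1798 without 6.

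The NLS libraries labelled t48 and t6 differed in 3673 genes, 1904 higher and 1769 lower at t48, 712 of them by at least 2-fold. Matrix genes were again higher, 17 of 23 with 1 lower (19 and 2 adjusted over the list alone): Thbs2 (log2 fold change 1.75), Col3a1 (1.67) and Col6a2 (1.48), against Bgn (-0.29), at adjusted p = 2.2e-23, and adjusted p = 0.0418 with an estimated correlation. Fibroblast markers had 4 higher and 1 lower of 7, also adjusted over the list alone, at adjusted p = 2.38e-07, and adjusted p = 0.0102 with an estimated correlation. ERK output genes had 12 lower and 1 higher of 18 (13 and 2 adjusted over the list alone): Ccnd1 (-0.65), Etv4 (-0.84) and Epha2 (-0.87), against Spry1 (2.14), at adjusted p = 2.02e-06, and adjusted p = 0.0737 with an estimated correlation. In all 9 of 25 lists passed with camera, and 2, matrix and fibroblast, with an estimated correlation. Of the other 6, sterol synthesis (11 lower of 20), G1/S (11 lower and 1 higher of 24) and G2/M genes (7 lower of 23) were lower, and the integrated stress response (11 higher of 20), glycolysis (9 higher and 2 lower of 22) and chaperones (8 higher of 15) higher. Adjusted over the list alone the counts were 11, 16 and 1, 7, 16, 14 and 3, and 8. Their adjusted p was 5.93e-05, 0.000928, 0.0128, 0.00148, 0.00103 and 0.0243, and adjusted p = 0.22, 0.593, 0.722, 0.593, 0.529 and 0.559 with an estimated correlation.

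Among single genes at the labelled t48 against t6, Igfbp5, an IGF-binding protein gene, was higher (log2 fold change 5.82, SE 0.32) and Cntn2, a neural adhesion gene, at 48.7 ± 14.1 against 0.222 ± 0.063 CPM; Nos1, Megf6 and Spats2l were also higher. Cadm1 had no reads at t48 and was at least 61.2-fold lower. Unc5c (-4.97), Gbp2b (-3.26), Ramp3 (-3.03) and Etv1 (-2.85) were lower. Without line 6 Bgn (-0.29) and Ramp3 did not pass (adjusted p = 0.0922 and 0.11). Ccn2 (408.3 ± 123 against 154.1 ± 73.8 CPM, adjusted p = 0.033) and Mitf (-0.64, adjusted p = 0.00684) passed, and Ccn1 (0.17, adjusted p = 0.569) only with the block (adjusted p = 0.0235). The call of Ccn2 was lost in 5 of 9 fits that left out a library or a line (adjusted p up to 0.199, without line 6), and that of Mitf without line 16 (0.105). YAP/TAZ targets as a list did not pass (adjusted p = 0.122; 0.00583 without line 16) and were higher with the block (adjusted p = 0.00031, and adjusted p = 0.387 with an estimated correlation and the block). TGF-beta targets (adjusted p = 0.362) were also higher with the block (adjusted p = 0.021, and adjusted p = 0.474 with an estimated correlation and the block). Without cell line 6 the count was 2043.

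Log2 fold changes at the labelled t6 and t48, both against the labelled t0, correlated across genes at r = 0.502. Simulated unchanged groups with shared t0 libraries gave r = 0.486 on average (0.431 to 0.536 over 20 simulations). The covariance was 0.267 against a simulated 0.0743 (0.0604 to 0.0873). Genes with a mean log2 CPM of at least 3 had a covariance of 0.0372 against a simulated 0.0124 (0.00651 to 0.0235), and r = 0.319 against a simulated r = 0.492 (0.281 to 0.723). Their simulated values were computed after the result was seen. Of all tested genes 62.87% had the same direction at both labels, below the simulated 65.68 to 67.55%. Calls overlapped in 678 genes higher and 357 lower, where independent lists would share 224 and 136, and 221 genes were called in opposite directions. The simulated groups shared 0, a count fixed by their having no changed genes, which does not measure how far the shared t0 libraries raise the overlap. The 3 t0 libraries do not divide into parts of at least 2, so no split was made, and part of the overlap may come from sharing them. Genes are not independent replicates.

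At the labelled t0, NLS and LacZ lines differed in 5669 genes, 2750 higher and 2919 lower in NLS, 1438 of them by at least 2-fold. Sterol synthesis genes were lower in NLS, 16 of 20 with 1 higher, also adjusted over the list alone, among them Msmo1 (log2 fold change -1.11), Mvd (-1.20) and Fdps (-0.80), with Cyp51 (0.32) higher. ERK output genes had 10 lower and 1 higher of 18 (11 and 1 adjusted over the list alone), with Spry4 (-3.42), Etv4 (-1.61) and Egr1 (-1.19) lower and Spry1 (2.04) higher. Cyp51 lost its call in 6 of 10 fits that left out a library or a line (adjusted p up to 0.12, without line 10) and Spry1 in 2 (up to 0.0508, without the LacZ t0 library of line 10). These lists had adjusted p = 6.63e-06 and 0.00102, and adjusted p = 0.343 for both with an estimated correlation. Matrix genes had 13 higher and 4 lower of 23, also adjusted over the list alone (adjusted p = 4.53e-07, and adjusted p = 0.343 with an estimated correlation). Of 22 cAMP and CREB targets 3 were higher and 9 lower (4 and 10 adjusted over the list alone). That list did not pass (adjusted p = 0.46; with fry it was lower at adjusted p = 0.016). Bmp4, a growth factor gene, Wnt5a, Fndc1, Cacna1c and Ereg had no LacZ t0 reads and were at least 88.8, 84.4, 91.5, 74.5 and 59.7-fold higher in NLS. Cadm1 was at 0.0295 ± 0.0511 CPM in NLS (n = 3) and 80 ± 2.57 CPM in LacZ (n = 2), Armcx2 at 0.12 ± 0.09 and 108.9 ± 1.48 CPM, and Gpr149, Prelid2 and Arap3 were near 0 in NLS as well. Adcy10 was at 188.9 ± 183 CPM in NLS and 0.13 ± 0.04 CPM in LacZ (adjusted p = 0.105; 0.000697 without line 16). No block can be fitted between different lines.

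Because Adcy10 reads followed the cell line number, libraries were also compared between the labelled cell line numbers, with the time label as a block. This comparison was chosen after the data were seen. By the labels each side is a single cell line, with its libraries under the different time labels as replicates. The p-values therefore do not measure the spread between lines, and cannot tell Adcy10 from any other difference between the lines. Line 6, with most Adcy10 reads, differed from line 16 in 295 genes, 115 higher and 180 lower. Adcy10 was higher by 8.44 on the log2 scale (SE 0.11, adjusted p = 1.01e-14). Some genes of cAMP signalling were higher. Pde4b, a cAMP phosphodiesterase gene, was at 15.9 ± 4.05 against 3.9 ± 2.08 CPM (SD over 3 time labels; log2 fold change 2.06, SE 0.18), and Sik1, a CREB-induced kinase gene (1.16, SE 0.10), Nr4a2 (1.15, SE 0.14), Pde4d (0.92, SE 0.08) and Pde3b (0.48, SE 0.05) were higher. Of 22 cAMP and CREB targets 6 were higher and none lower (9 and 2 adjusted over the list alone; adjusted p = 3.81e-09, and adjusted p = 0.285 with an estimated correlation and 0.0526 with fry). Of the cAMP machinery 3 of 23 were higher, also over the list alone (adjusted p = 0.000493, and adjusted p = 0.366 with an estimated correlation). This list shares Pde4b and Pde4d with the cAMP and CREB targets, so the lists are not separate results. Nr4a1 (1.45, adjusted p = 0.0868; 0.000455 without t0) and Crem (0.25, adjusted p = 0.639) did not pass. In LacZ t0, with almost no Adcy10 reads, Nr4a2 was at 10.88 and 10.79 CPM, above every NLS library (up to 9.503 CPM). Nr4a1 there was at 12.92 and 11.49 CPM, against 11.25 to 13.59 CPM in line 6. Pde4d reached 20.67 CPM in LacZ t48, while Sik1 stayed at up to 11.87 CPM in the LacZ lines, below every NLS library (14.13 CPM or more). Also higher in line 6 than in 16 were Adgrg1 (1.91), Olfr1307 (1.90), Vdr, the vitamin D receptor gene (1.88), Cxcl1 (1.52) and Apold1 (1.28). Lower were Pdgfb (-0.95), Cdk5r1 (-0.80), Slc16a3 (-0.75), Dlk2 (-0.64), Gpr35 (-0.62) and Tjap1 (-0.62). In 3 fits that left out the libraries of a time label, Slc16a3 lost its call in all 3 (adjusted p up to 0.133), Gpr35 and Pdgfb in 2 (up to 0.433 and 0.189), and Apold1, Cdk5r1 and Dlk2 in 1 (0.297 and 0.114 without t48, and 0.101 without t6). YAP/TAZ targets had 5 lower and 1 higher of 22 (7 and 1 adjusted over the list alone), with Ccn1 (-0.53), Ccn2 (-0.59), F3 (-0.42) and Arhgef17 (-0.32) lower and Igfbp3 (0.17) higher, at adjusted p = 9.56e-05, and adjusted p = 0.382 with an estimated correlation. Igfbp3 lost its call in all 3 fits (adjusted p up to 0.234), Ccn2 without t0 (0.108) and Arhgef17 without t6 (0.119). Yap1 (0.01, adjusted p = 0.937), Mitf (-0.04, adjusted p = 0.958) and Cdkn1a (-0.20, adjusted p = 0.446) did not pass. Of 25 lists 7 passed with camera, and 0 with fry or an estimated correlation. Without the time label as a block edgeR called 1 gene (263 at an unadjusted p below 0.05).

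Line 7 differed from line 16 in 2950 genes, 1543 higher and 1407 lower, with 9 called without the time block (1196 at an unadjusted p below 0.05). Pde4b (log2 fold change 2.48, SE 0.18), Pde4d (0.78, SE 0.08) and Sik1 (0.57, SE 0.10) were higher and Nfil3 (-0.40, SE 0.06) lower. cAMP and CREB targets had 5 higher and 1 lower of 22 (5 and 2 adjusted over the list alone) and the list did not pass (adjusted p = 0.0757; 0.00675 without t0). G2/M genes had 17 higher and none lower of 23, also adjusted over the list alone, with Cenpf (0.44), Top2a (0.32) and Ube2c (0.24), at adjusted p = 1.85e-08, and adjusted p = 0.333 with an estimated correlation. Interferon-stimulated genes had 13 higher and none lower of 26 (15 adjusted over the list alone), with Mx1 (1.35), Ifit1 (1.22) and Ifi44 (0.78), at adjusted p = 2.89e-05, and adjusted p = 0.433 with an estimated correlation. YAP/TAZ targets had 9 lower and 1 higher (10 and 2 adjusted over the list alone), with Ccn2 (-1.13), Ccn1 (-0.39) and Tgfb2 (-0.76) lower and Igfbp3 (0.46) higher, at adjusted p = 0.000403, and adjusted p = 0.433 with an estimated correlation. Id2 (-0.41) and the cell cycle inhibitor gene Cdkn1a (-0.75) were lower, and Bmp4 (0.42) higher, a call lost in 2 of 3 fits that left out the libraries of a time label (adjusted p up to 0.103, without t48). Transcripts encoded by mitochondrial DNA had 4 of 13 higher, mt-Atp8 (2.89), mt-Atp6 (1.49), mt-Nd2 (0.75) and mt-Nd1 (0.51), also adjusted over the list alone, at adjusted p = 0.00071, and adjusted p = 0.457 with an estimated correlation; the share of reads from mitochondrial DNA was highest in line 7 under each time label. All 4 genes lost their calls in each of the 3 fits without a time label (adjusted p up to 0.24, 0.243, 0.153 and 0.228, without t0). Of 25 lists 14 passed with camera, 15 with fry and 0 with an estimated correlation.

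Line 7 differed from line 6 in 1446 genes, 769 higher and 677 lower, and edgeR called 0 without the time block (556 at an unadjusted p below 0.05). cAMP and CREB targets had 1 higher and 5 lower of 22 in line 7 (3 and 7 adjusted over the list alone), and the list was lower at adjusted p = 0.0185, and adjusted p = 0.51 with an estimated correlation. It did not pass without t0 (adjusted p = 0.157) or with fry (0.0906). Of 25 lists 11 passed with camera, 4 with fry and 0 with an estimated correlation. LacZ line 12 differed from line 10 in 16 genes, 12 higher and 4 lower, among them Adgrg1 (1.78), Car6 (0.93) and Txnip (-0.63). Without LacZ t0 Car6 and Txnip did not pass (adjusted p = 0.235 and 0.277), and edgeR called 0 without the time block (184 at an unadjusted p below 0.05). Although both LacZ lines have almost no Adcy10 reads, camera passed 8 of 25 lists between them, and fry and an estimated correlation 0. Among the 8, the cAMP machinery, YAP/TAZ targets and the integrated stress response were higher in line 12 at adjusted p = 0.0273, 0.0173 and 4.07e-08, and adjusted p = 0.742, 0.778 and 0.676 with an estimated correlation. None of the 3 passed without LacZ t0 (adjusted p = 0.224, 0.436 and 0.237). No member of these 3 lists passed over all genes. cAMP and CREB targets did not pass (adjusted p = 0.857).

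**Figure D4:**
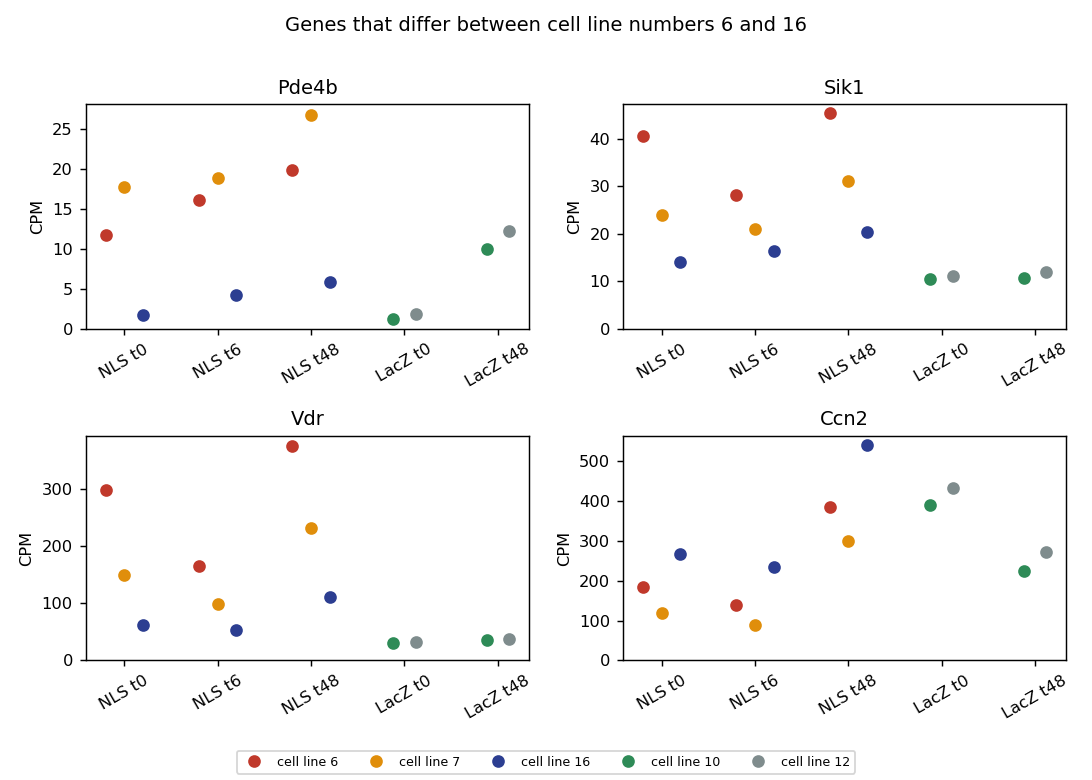
Level in CPM of Pde4b, Sik1, Vdr and Ccn2 in each of the 13 libraries, by labelled group, with points coloured by cell line number and axes starting at 0. Under each of the 3 NLS time labels, lines 6 and 7 lie above line 16 for Pde4b, Sik1 and Vdr and below it for Ccn2. Pde4b averaged 1.59 CPM in LacZ t0 and 11.1 CPM in LacZ t48. It was higher at t48 in both LacZ lines (9.949 against 1.287 CPM in line 10, 12.18 against 1.898 CPM in line 12). The edgeR fit without the block by cell line did not call it (adjusted p = 0.176).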

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

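The interaction was planned, while the tests of exchanged labels, of Adcy10 induction and of a response common to NLS and LacZ lines were chosen only after the result was seen.

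The t48 response differed between NLS and LacZ lines in 3045 genes by the test of the difference itself, and the results below stand out by the same test. For gene lists the adjusted p was 3.37e-08 for antigen presentation, 5.1e-06 for interferon-stimulated genes and for matrix genes, 1.07e-05 for sterol synthesis, 4.57e-05 for glycolysis and hypoxia, 0.000129 for G2/M, 0.000343 for G1/S, 0.000857 for fibroblast markers and 0.0495 for YAP/TAZ targets. Antigen presentation alone passed with an estimated correlation (adjusted p = 0.0415). The other 8 did not, at adjusted p = 0.496, 0.414, 0.218, 0.354, 0.496, 0.496, 0.0706 and 0.496 in the order given. Among single genes whose difference was more positive in NLS lines, the adjusted p was 6.81e-10 for Setbp1, 9.35e-07 for Robo1, 1.08e-06 for Zdhhc15, 1.67e-05 for Dact2, 4.39e-05 for Spats2l, 0.00117 for Spry1, 0.0172 for Adam23 and 0.0368 for Vat1l. Among those more negative it was 1.96e-10 for Tspan7, 3.99e-06 for Akr1c13, 7.62e-06 for Unc5c, 0.000192 for Prkg1, 0.000467 for Slurp1, 0.0208 for Ptx3, 0.0298 for Abi3bp and 0.0473 for Cacna1c. Of 15 fits that left out a library or a line, the call was lost in 11 for Cacna1c, 9 for Abi3bp, 6 for Ptx3 and Vat1l and 2 for Adam23. The LacZ change of Adam23 rests on 1 read, in the LacZ t0 library of line 10.

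Within the NLS and within the LacZ libraries, some genes were on in all lines under 1 time label and off in all under another. Adcy10 reads in the NLS libraries followed the cell line number. Induction of Adcy10 mRNA at the labelled times, as counted on the mouse transcripts, is argued against in lines 6 and 7 by its ratio to the labelled t0, at most 1.02. In line 16 it stays open: the ratios were 1.78 and 1.82 at up to 1.22 CPM, with overlapping counting intervals. With the labels as given, a response to doxycycline or time alike in NLS and LacZ lines is argued against as the whole cause by the correlation of their t48 fold changes across genes, r = -0.0577. A common part stays open, as the overlap of calls cannot decide it. In both, 223 genes were higher and 203 lower, above the 168 and 145 of independent lists, but opposite calls were also above, 486 against 318. Among genes called in either, the fold changes correlated at r = -0.127. An exchange of time labels and cell line numbers stays open: the fewest on/off genes between 2 time labels (3) were 1.5 times the most between 2 line numbers (2), between the bounds set for and against it (over 5 times, and at most equal). A response to doxycycline in NLS lines that is separate from Adcy10 mRNA was not tested, nor was expression of the construct without doxycycline.

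Of 22 cAMP and CREB targets 6 were higher in cell line number 6 than in 16, and the list passed with camera. With an estimated correlation the list had an adjusted p = 0.285, and with fry 0.0526. The order of Adcy10 reads was not kept throughout. Pde4b was higher against line 16 in line 7 (log2 fold change 2.48) than in line 6 (2.06). In the LacZ lines Pde4b was at 1.287 and 1.898 CPM at t0 and averaged 11.1 CPM at t48. Nr4a2 was higher in both LacZ t0 libraries (10.88 and 10.79 CPM) than in any NLS library. Greater depth of line 6 is argued against. At t6 line 6 had fewer reads than line 16 (21070676 against 21583006), and with all libraries thinned to the same total the list kept an adjusted p = 1.63e-09, and adjusted p = 0.268 with an estimated correlation. The exchange of labels stays open here too. It needed the list to pass in line 7 against 16 as well, where the adjusted p was 0.0757 (0.0479 after thinning, and adjusted p = 0.408 with an estimated correlation). After thinning, fry gave adjusted p = 0.0464 for 6 against 16 and 0.0422 for 7 against 16. It also needed no rise of the list between time labels. Camera called none at t6 or t48, apart from t6 without line 6 (adjusted p = 0.0316). Fry called the list higher at both, at adjusted p = 0.0414 and 0.0206. By the labels as given, lines 6, 7 and 16 already differed at t0, before doxycycline. Pde4b was at 11.73, 17.73 and 1.677 CPM in that order, Sik1 at 40.58, 23.97 and 14.13 CPM, and Pde4d at 21.95, 21.22 and 11.5 CPM. Nr4a1, at 13.59, 3.624 and 4.216 CPM, was not higher in line 7 than in line 16. Each of these values is from 1 library, and the difference at t0 was not tested.

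With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real split and the highest other split called 2716 and 1 genes for NLS t6 against t0, 3402 and 0 for NLS t48 against t0, and 3673 and 0 for NLS t48 against t6. They called 295 and 32 for line 6 against 16, 2950 and 0 for line 7 against 16, and 1446 and 5 for line 7 against 6. Every other split mixes libraries of both compared groups, so a difference between the groups widens the spread within its sets. Low counts of the other splits therefore do not show how many genes an arbitrary grouping would call.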

How the results depend on the processing

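The tests between cell line numbers, all with the time label as a block or without it, were chosen only after the result was seen, and the others were planned.

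The block by cell line called 4527 genes at t6, 5188 at t48, 4308 in LacZ and 4875 for the interaction; it cannot be estimated for NLS t0 against LacZ t0. At least 2-fold left 424 (t6), 664 (t48), 483 (LacZ), 859 (interaction), 712 (t48 against t6) and 1438 (NLS t0 against LacZ t0), and 26, 131, 47 and 3 for lines 6 against 16, 7 against 16, 7 against 6 and 12 against 10, by construction. Only the groups compared, with fewer libraries, gave 1805 at t6, below the main count, and 2712 in LacZ, above the main 2419. Without the time block edgeR called 1, 9, 0 and 0 between those lines (263, 1196, 556 and 184 at an unadjusted p below 0.05). DESeq2 called 1675 for 7 against 16, 835 for 7 against 6 and 45 for 12 against 10, and no filter 83 for the last. Without the t6 or t48 libraries 6 against 16 gave 174 and 127; without t0 or t48, 7 against 16 gave 1528 and 1500, and 7 against 6 gave 476 and 785; without LacZ t0, 12 against 10 gave 8. Adcy10 between NLS t0 and LacZ t0 passed with DESeq2 (log2 fold change 10.51, adjusted p = 1.94e-05). Unless the construction shows it, the cause was not tested.

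Leaving out libraries or lines, where a lone library is assumed to vary like the others, gave 988 (without line 6) to 2818 genes at t6, 1596 (without 6) to 3063 at t48, 533 (without 10) to 1309 in LacZ, 1296 (without 10) to 3166 for the interaction, and 2043 (without 6) to 3330 for t48 against t6. The log2 fold change of Adcy10 ranged from -1.06 to 0.86 at t6, -0.91 to 0.83 at t48, -4.49 to 0.35 in LacZ, -0.43 to 4.41 for the interaction, -0.87 to 0.99 for t48 against t6 and 9.55 to 11.05 between NLS t0 and LacZ t0. The ends -4.49 and 4.41 come from a fit whose only LacZ t48 library had 0 Adcy10 reads. Its floor, 0.154 CPM, lies above the LacZ t0 mean of 0.13 CPM, so they show no decrease. At t6 Ccn1 ranged from -0.18 to 0.20, Ccn2 from -0.74 to 0.02, Cdkn1a from -0.15 to 0.31 and Nr4a1 from -0.067 to 1.17. At t48 Cdkn1a ranged from -0.14 to 0.30 and Nr4a1 from -0.23 to 1.02, and for t48 against t6 from -0.20 to 0.21 and -0.47 to 0.23. Mitf in LacZ ranged from -0.23 to 0.23, and Yap1 between NLS t0 and LacZ t0 from -0.024 to 0.031.

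Directions turned for genes that did not pass: Mitf in LacZ (-0.0013 without a filter, -0.35 with counts from TPM) and in the interaction (0.11 with counts from TPM), and Yap1 at t48 against t6 (0.017) and NLS t0 against LacZ t0 (-0.035), both with counts from TPM. Between lines, Mitf turned in 6 against 16 without t0 (0.081) or t6 (0.0065), and in 7 against 16 without t48 (-0.075), and Yap1 in 6 against 16 without t48 (-0.023).

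Of 25 lists, an estimated correlation left 0 at t6 and t48 (4 and 3 at an unadjusted p below 0.05), 1 in LacZ and the interaction, 2 at t48 against t6, 0 for NLS t0 against LacZ t0 (3 unadjusted), and 0 between each pair of lines (1, 3, 2 and 1 unadjusted). Fry called 15 at t6, 10 at t48, 16 for the interaction, 15 for t48 against t6 and for NLS t0 against LacZ t0, and 0, 4 and 0 for lines 6 against 16, 7 against 6 and 12 against 10 (6, 10 and 3 unadjusted). The block gave 12 at t6 and 7 at t48. Leaving out a line gave 7 to 11 at t6 and 3 to 5 for NLS t0 against LacZ t0, and leaving out LacZ t48 gave 5 for 12 against 10.

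The adjusted p of cAMP and CREB targets with fry was 0.0414 (higher) at t6, 0.0206 (higher) at t48, 0.016 (lower) for NLS t0 against LacZ t0, 0.0526 for 6 against 16, 0.0906 for 7 against 6 and 0.992 in LacZ, where it turned. With an estimated correlation it was 0.285 for 6 against 16 and 0.51 for 7 against 6. Without t0 it was 0.00675 for 7 against 16 and 0.157 for 7 against 6. Leaving out a line gave 0.0316 (without 6) to 0.411 at t6 and 0.869 to 0.909 in LacZ. For YAP/TAZ targets fry gave 0.0231 at t48, 0.0259 at t48 against t6, 0.0987 for 6 against 16 and 0.583 for 12 against 10. The block gave 0.909 at t6, where it turned, 0.000318 at t48 and 0.00031 at t48 against t6. An estimated correlation gave 0.496 for the interaction, 0.382 for 6 against 16, 0.433 for 7 against 16 and 0.778 for 12 against 10. Without t48 it was 0.000553 for 7 against 6 and without LacZ t0 0.436 for 12 against 10. Leaving out a line gave 0.757 to 0.98 at t6, 0.00306 (without 16) to 0.188 at t48, 0.00125 to 0.179 for the interaction, 0.00583 (without 16) to 0.0971 at t48 against t6 and 0.572 to 0.934 for NLS t0 against LacZ t0. Interferon genes turned in 12 against 10 without LacZ t48 (0.24). Among genes with a mean log2 CPM of at least 3 the t6 and t48 responses correlated at r = 0.319, within the simulated 0.281 to 0.723. Their covariance, 0.0372, lay above the simulated 0.00651 to 0.0235, which were computed after the result was seen.

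Of 4358 values of named genes under alternatives, the level of Adcy10 left out, 3988 kept direction and side of the threshold, 302 lost the call, 31 gained it and 37 turned. Of 512 list values 369 kept both, 123 lost the call, 12 gained it and 8 turned. Genes at a few reads, such as Adcy10 in line 16 and the LacZ lines, are limited by depth.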

Other observations

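The comparisons between cell line numbers, and the tests of exchanged labels, were chosen only after the result was seen, whereas the gene lists here were planned.

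Genes of further lists differed between the libraries labelled NLS t48 and t0 without the list passing. Tead2, which encodes a partner of YAP, was higher (log2 fold change 2.55, SE 0.08), as were the phosphodiesterase gene Pde3a (3.83, SE 0.38), the apoptosis gene Pmaip1 (3.75, SE 0.36) and the melanosome gene Gpnmb (1.22, SE 0.15). The list's adjusted p was 0.223 for the Hippo pathway, 0.539 for the cAMP machinery, 0.216 for p53 targets and 0.252 for pigment genes. It was 0.982 for dedifferentiation, CDK inhibitors and keratinocyte markers, 0.281 for the integrated stress response, 0.539 for chaperones, 0.181 for mitochondrial DNA and for TGF-beta targets, 0.223 for the nuclear-encoded respiratory chain, 0.783 for Wnt targets, 0.697 for antigen presentation, 0.341 for ERK output and 0.51 for leukocyte markers (2 tested).

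Across the 13 libraries Mlana, Pmel and Dct, pigment genes, reached at most 0.0499, 0.358 and 0.307 CPM. Col3a1 lay between 1630 and 5630 CPM, Postn between 27.6 and 593 CPM, Krt14 between 0.111 and 2.87 CPM and Pecam1 between 2.1 and 4.22 CPM. Other fibroblast genes went both ways. Pdgfrb lay between 161 and 221 CPM, Pdgfra between 12.5 and 256 CPM and Col1a2 between 2030 and 4570 CPM. Dcn lay between 3.13 and 18.5 CPM, while Fap, Thy1 and Lum reached at most 0.425, 0.0942 and 0.0536 CPM.

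Between libraries of all cell lines with at least 2 CPM under 1 time label and at most 0.2 CPM under another there were 9 genes for NLS t6 and t0, 14 for t48 and t0, 3 for t48 and t6, and 7 for LacZ t48 and t0. Between cell line numbers there were 0 for 6 and 16, 2 for 7 and 16, 1 for 7 and 6, and 2 for 12 and 10. Of the squared deviations from each gene's mean log2 CPM in the 9 NLS libraries, the time label took 56.6% and the line number 18.6%. An arbitrary grouping into 3 sets of 3 libraries would also take a share. That share was not computed, so 18.6% does not by itself show an effect of the line number. As a hypothesis, the numbers titled as cell lines may stand for times and the titled times for lines; the ratio of 1.5 between the counts and the adjusted p = 0.0757 of cAMP-responsive genes in line 7 against 16 leave it undecided. If it holds, the comparisons by time label compare cell lines.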
